A study of Mus musculus with 13 samples.

How the data were processed

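RNA from mouse cells and tissue was measured on 1-colour Agilent expression arrays with Cy3 label, 1 sample per array. The 13 arrays held mouse embryonic fibroblasts (MEF, 2 arrays), tail tip fibroblasts (TTF, 2 arrays), induced embryonic Sertoli cells made from TTF (TTF-ieSC, 2 arrays) or from MEF (MEF-ieSC, 1 array), male gonads at 14.5 days post coitum (2 arrays), immature Sertoli cells from 19 dpc testis (2 arrays) and mature Sertoli cells from testis at 8 weeks (2 arrays). The study's design text gives duplicates for every group; another MEF-ieSC array was not analysed here. Whether replicates came from separate animals, cultures or labellings is not given.

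The authors deposited 1 table of log2 signal for all 62976 features of the array, already brought to the same distribution on every array. The sorted values are nearly identical between arrays, and every array had a minimum of 0.566, a median of 7.488, a 75th percentile of 10.473 and a maximum of 18.872. Per the submitters' processing notes, limma was used, with no version or role stated. The feature extraction, the background correction and any floor are not given in the sources used here, and the table holds no detection flags and does not mark control features. Values near or under the array median are therefore dim by rank, and a fold against such a value depends on a background that is not known. No depth can be given for an array, so the number of arrays limits the precision.

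Features were named through the platform annotation, and symbols were updated through a RefSeq gene table of assembly GRCm38.p6, which served for names and chromosomes. Of the features, 31465 had 1 symbol, 0 had several and 31511 had none. Updating matched 29036 by accession, 2075 by symbol and 349 by an older name, and 5 kept the platform's name; 3282 symbols changed. This gave 20738 genes, of which 6171 had more than 1 feature. A gene with several features was represented by the feature with the highest mean over the 13 arrays. Genes above the array median on at least 2 arrays were tested, 16658 in all.

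Each comparison was fitted on the log2 values with lmFit and eBayes of limma 3.58.1 in R 4.3.3. All 13 arrays and 7 groups entered 1 fit, with 6 residual degrees of freedom and 2.18 prior degrees of freedom. The single MEF-ieSC array was assumed to vary like the other groups. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and a gene was called at an adjusted p under 0.05. Errors beside log2 differences are standard errors of that fit. They and the p-values measure only the spread between these arrays, which may be technical.

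A total of 29 gene lists, with 615 of their 638 genes on the array, was tested with camera at a preset correlation of 0.01, adjusted over the lists within a comparison. Each list's counts were taken over all genes and adjusted over the list alone. For the native signature, genes called with a log2 difference of 1 or more in size between native cells and 1 fibroblast type were read in the induction from the other fibroblast type, with which they share no array. The p-values of these 12 sets were adjusted together by Benjamini-Hochberg, an adjustment added after the data were examined. The distance between groups was the root mean square of the log2 differences of their means over tested genes.

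The groups, comparisons, gene lists, alternatives and the rule for named genes were fixed before the data were examined. For each of 6 main comparisons the rule took the 5 factors, the 6 genes with the largest rise and the 6 with the largest fall among calls whose arrays did not overlap between the groups, the 2 most changed called members of the 6 lists with the smallest p, and a set of 10 markers. Clone and predicted names were left out. Another alternative, leaving out features in uneven blocks of the array grid, was chosen after seeing the data.

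The fit was tested on simulated data with 200 changed genes among the 16658 tested, 50 per size. For TTF-ieSC against TTF it recovered 64%, 86%, 96% and 98% of genes changed by 0.5, 1, 2 and 4 on the log2 scale, and called 3 of 16458 unchanged genes. For MEF-ieSC against MEF the shares were 38%, 92%, 84% and 100%, with 6 unchanged genes called. None of 28 unchanged simulated lists was called in either. The simulated noise was independent between genes, the lists were drawn at random, and a gene's spread was the same on every array. The simulation therefore does not give the rate of false calls for correlated gene lists or for a MEF-ieSC array that varies otherwise. It also changed far fewer genes than the 12444 called in TTF-ieSC against TTF. The Benjamini-Hochberg cutoff depends on the share of genes changed, so neither the recovery nor the false calls carry over to these data.

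The alternatives were quantile normalization, a common 75th percentile, no filter, a filter at the 75th percentile, the mean of a gene's features, a minimum log2 difference of 1, a variance trend with robust fitting, a fit on the compared groups alone, a replicate block, array weights, leaving out each array in turn, and camera with an estimated correlation. Tables were handled with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. Features with no gene name were left out of the gene tests.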

Results

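Gene expression was measured on 13 arrays of mouse cells in 7 groups. Fibroblasts from embryos (MEF, 2 arrays) or from tail tips (TTF, 2 arrays) were the starting cells. Induced embryonic Sertoli cells (ieSC) had been made from them with Nr5a1, Wt1, Dmrt1, Gata4 and Sox9, transcription factors of the developing gonad (TTF-ieSC, 2 arrays; MEF-ieSC, 1 array). The native samples were whole male gonad at 14.5 dpc, immature Sertoli cells at 19 dpc and mature Sertoli cells at 8 weeks, 2 arrays each. Culture differed between the groups. The fibroblasts were grown for 3 passages in 10% serum and the induced cells for 6 months in 2% serum with doxycycline. Serum and culture therefore differ between them along with the factors. The immature and mature Sertoli cells were grown for 3 and 7 days in 10% serum, and the gonad was not cultured. The values were deposited log2 signals with an array median of 7.488 on every array, and the replicate arrays of a group lay 0.167 to 0.310 apart (root mean square log2 difference over the 16658 tested genes).

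The comparison of TTF-ieSC with TTF asked how the induced cells differed from the tail tip fibroblasts they came from. No group here held fibroblasts cultured like the induced cells without the factors. Effects of the factors therefore cannot be told apart from those of culture. Wt1 rose by 9.67 ± 0.06 (log2 difference ± SE) to a level of 16.48, above the 15.64 of immature Sertoli cells, and Nr5a1 rose by 1.09 ± 0.09 (adjusted p = 3.97e-06) to 9.37, against 13.89 in immature Sertoli cells. Sox9 fell by 1.52 ± 0.07, while Gata4 (difference -0.27, adjusted p = 0.132) and Dmrt1 (0.07, adjusted p = 0.412) did not pass the test. The Gata4 difference passed it, at -0.49 (adjusted p = 0.00839), without TTF-ieSC replicate 2. Which part of a transcript a feature reads is not given, so these values do not separate a transgene from the cell's own gene.

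Fibroblast genes were lower and embryonic Sertoli cell genes were higher in the TTF-derived cells. Of 39 fibroblast identity genes, 36 fell and 1 rose (adjusted p = 3.76e-14), among them Thy1, a fibroblast surface antigen (-11.54 ± 0.16), and Lox, which crosslinks collagen (-9.66 ± 0.06). Col1a1, a main fibrillar collagen, fell by only 1.19 ± 0.06 and stayed at 16.13. Of 34 embryonic Sertoli cell markers, 22 rose and 4 fell (adjusted p = 0.00131). The prostaglandin D synthase Ptgds rose by 11.23 ± 0.06, the keratin Krt18 by 9.24 ± 0.08, Tesc by 8.78 ± 0.08 and the secreted ligand Dhh by 6.03 ± 0.06. Amh, the hormone that removes the Müllerian duct, rose by 0.92 ± 0.19 (adjusted p = 0.00224) to 7.36, near the array median, against 12.34 in the gonad. The tight junction gene Cldn11 rose by 1.14 ± 0.06 to 8.09, against 15.47 in immature Sertoli cells.

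Genes of cell division and cholesterol synthesis rose, and genes of smooth muscle, interferon response and inflammation fell. Of 38 cell division genes, 36 rose and 2 fell (adjusted p = 1.40e-10), with the replication helicase gene Mcm3 up by 3.43 ± 0.08 and Mki67 by 3.27 ± 0.04. Of 20 cholesterol synthesis genes, 18 rose and 1 fell (adjusted p = 0.000195), Tm7sf2 by 1.87 ± 0.06 and Stard4 by 1.67 ± 0.08. Against the uncultured gonad that list had 7 higher and 7 lower in TTF-ieSC (adjusted p = 0.949), and it did not pass in MEF-ieSC against MEF (10 higher and 2 lower, adjusted p = 0.0577). Of 30 interferon response genes, 26 fell and 3 rose (adjusted p = 2.56e-08), with Ifih1, a sensor of double-stranded RNA, at -7.28 ± 0.23 and Oas1a at -7.21 ± 0.11. Of 16 smooth muscle genes, 15 fell and 1 rose (adjusted p = 1.40e-05), with the contractile genes Myl9 at -7.27 ± 0.06 and Actg2 at -5.58 ± 0.06. Of 23 inflammatory factors, 16 fell and 6 rose (adjusted p = 0.00205). All of these 7 lists passed the test with an estimated correlation too, with adjusted p from 0.00239 to 0.0381, and adjusted over the list alone their counts were the same. The list of 26 mature Sertoli cell markers, with 16 higher and 8 lower, did not pass (adjusted p = 0.245), nor did the 27 epithelial genes, with 16 higher and 7 lower (adjusted p = 0.0864).

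Beside Ptgds, Wt1 and Krt18, the largest rises among the named genes were those of P2rx2, a channel opened by ATP (9.83 ± 0.09), and the phosphate transporter gene Slc34a3 (9.39 ± 0.64), whose TTF arrays were dim and varied (6.38 ± 1.73, SD). With Thy1, the largest falls among them were those of the BMP antagonist Grem1 (-11.93 ± 0.27), the chemokine Cxcl12 (-11.68 ± 0.07), the microfibril gene Mfap5 (-11.42 ± 0.10), Hoxb13 (-11.18 ± 0.21) and the imprinted non-coding RNA Meg3 (-10.53 ± 0.11). Meg3 has 3 features, with changes from -10.53 to -3.75 here and from -10.31 to -3.94 in MEF-ieSC against MEF. Xist, the RNA of the inactive X chromosome, fell by 4.31 ± 0.33 to 5.53. Rhox5 rose by 0.81 ± 0.09. Fshr, the receptor for follicle-stimulating hormone, was dim in both groups (6.38 against 4.74), and its rise of 1.64 ± 0.53 (adjusted p = 0.0200) did not pass without TTF replicate 1 (adjusted p = 0.127) or TTF-ieSC replicate 1 (adjusted p = 0.0854). In all, 12444 genes were called, 6586 higher and 5858 lower, and 5615 of them differed by 1 log2 unit or more.

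**Figure D1:**
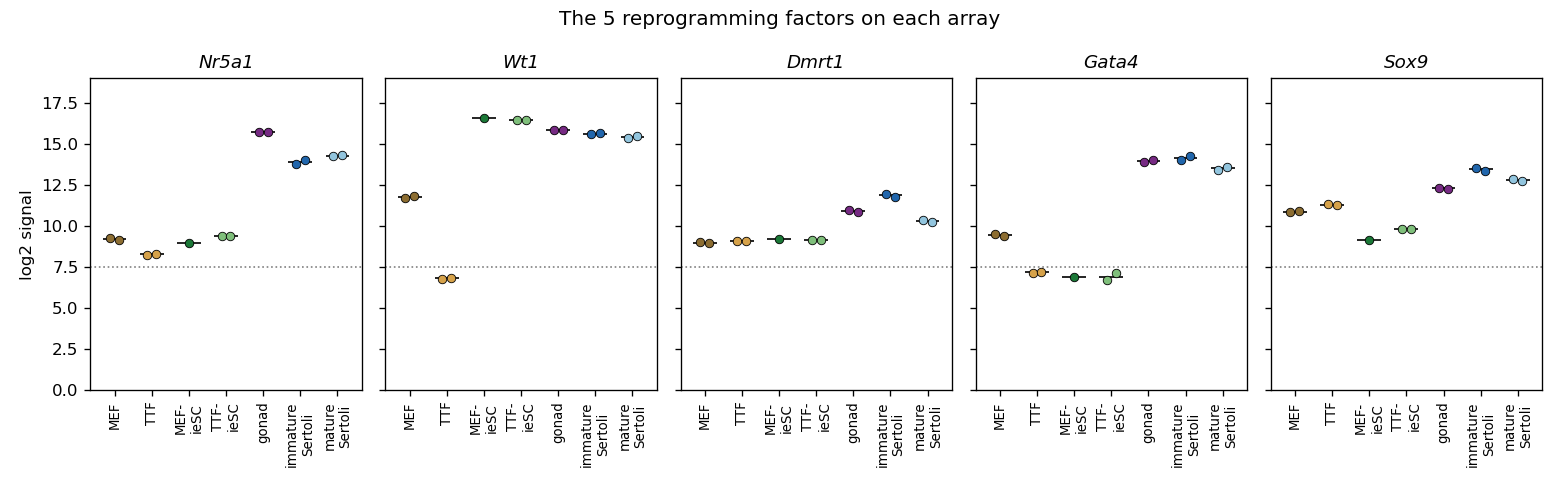
Log2 signal of the 5 factors on each array (points) with the group mean (bars) and the array median (dotted line). Wt1 lies between 16.48 and 16.58 in the induced cells, above the native samples, while Gata4 lies at 6.92 in both kinds of induced cell and between 13.51 and 14.16 in the native samples.

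The comparison of MEF-ieSC with MEF asked the same of embryonic fibroblasts, with 1 array of induced cells. Wt1 was already 11.77 in MEF and rose by 4.81 ± 0.08. Gata4 fell by 2.51 ± 0.18 and Sox9 by 1.76 ± 0.09. Nr5a1 (-0.26, adjusted p = 0.0559) and Dmrt1 (0.22, adjusted p = 0.0614) lay close to the threshold and passed it without either immature Sertoli array (adjusted p = 0.0165 and 0.0381). Both also passed with a filter at the 75th percentile (adjusted p = 0.0425 and 0.0492) and with a variance trend and robust fitting (adjusted p = 0.0347 and 0.0448). Nr5a1 passed with array weights (adjusted p = 0.0410) and without MEF replicate 2 (-0.33, adjusted p = 0.0402).

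The fibroblast list fell here too, with 35 of 39 genes lower and 3 higher (adjusted p = 1.46e-11), as Thy1 (-10.33 ± 0.20) and the matrix protease gene Mmp2 (-9.29 ± 0.10) show, and Col1a1 fell by 0.50 ± 0.07. Of the 34 embryonic Sertoli cell markers, 22 rose and 7 fell (adjusted p = 0.000859): Ptgds by 9.45 ± 0.08, Cst9 by 7.90 ± 0.75, Dhh by 7.25 ± 0.08, Krt18 by 4.04 ± 0.10, Amh by 1.43 ± 0.23 and Cldn11 by 1.12 ± 0.07. For Cst9 the MEF arrays were dim and varied (5.52 ± 1.69, SD). Amh was under the array median in both MEF (5.87) and MEF-ieSC (7.30), so its rise depends on the background. Smooth muscle genes fell, 15 of 16 with 1 higher (adjusted p = 5.35e-07), Actg2 by 8.76 ± 0.07 and Myl9 by 8.43 ± 0.07. Of 20 anterior and central Hox genes, which mark position along the body axis, 17 fell and 1 rose (adjusted p = 1.69e-06), Hoxc6 by 6.59 ± 0.10 and Hoxb2 by 6.55 ± 0.09. Of 29 imprinted genes, 23 fell and 5 rose (adjusted p = 0.00014), with Meg3 at -10.31 ± 0.13 and Dlk1 at -8.75 ± 0.08. Of 30 interferon response genes, 22 fell and 4 rose (adjusted p = 0.000194), with Ifi44 at -5.01 ± 0.43 and Ifih1 at -4.43 ± 0.28. The other feature of Ifih1 changed by -1.58 here and by -3.82 in TTF-ieSC against TTF. Of 38 cell division genes, 23 rose and 2 fell (adjusted p = 0.00347).

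These 7 lists passed with an estimated correlation (adjusted p from 0.00423 to 0.0404), and adjusted over the list alone their counts were the same. The macrophage list, with 19 of 23 genes lower and 2 higher (adjusted p = 0.00264), did not hold (adjusted p = 0.180 with an estimated correlation); adjusted over the list alone it had 19 lower and 3 higher. The junction list, 17 of 29 genes higher and 6 lower (adjusted p = 0.0264), did not hold either (adjusted p = 0.199 with an estimated correlation). The interstitial list (10 of 15 lower and 3 higher, adjusted p = 0.0138) and the inflammatory list (14 of 23 lower and 5 higher, adjusted p = 0.0148) each had an adjusted p = 0.0738 with an estimated correlation. For the junction, interstitial and inflammatory lists the counts adjusted over the list alone were the same. The Leydig cell list, with a median of -0.49, was called lower at the preset correlation and did not hold with an estimated correlation.

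Other large rises were those of Slc34a3 (10.62 ± 0.79), the homeobox gene Tlx2 (9.72 ± 0.19), P2rx2 (9.64 ± 0.11), Cidea (8.82 ± 0.14) and, between these, Wfdc18. With Thy1 and Meg3, the largest falls among the named genes were those of Adgra2 (-12.48 ± 0.52), Cxcl12 (-11.04 ± 0.08), Aldh9a1 (-10.30 ± 0.57) and Lrrc17 (-10.08 ± 0.13). Adgra2 and Aldh9a1 each have 1 feature, in a corner of the MEF-ieSC array where 121 neighbouring features had a median of -1.21 against the TTF-ieSC arrays. Rhox5 fell by 2.26 ± 0.11 and Xist by 3.73 ± 0.41. Fshr was dim in both groups, and its difference of -1.43 did not pass (adjusted p = 0.0798), though without MEF replicate 2 it was -2.36 (adjusted p = 0.00119). In all, 11318 genes were called, 5714 higher and 5604 lower, and 4860 of them differed by 1 log2 unit or more.

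**Figure D2:**
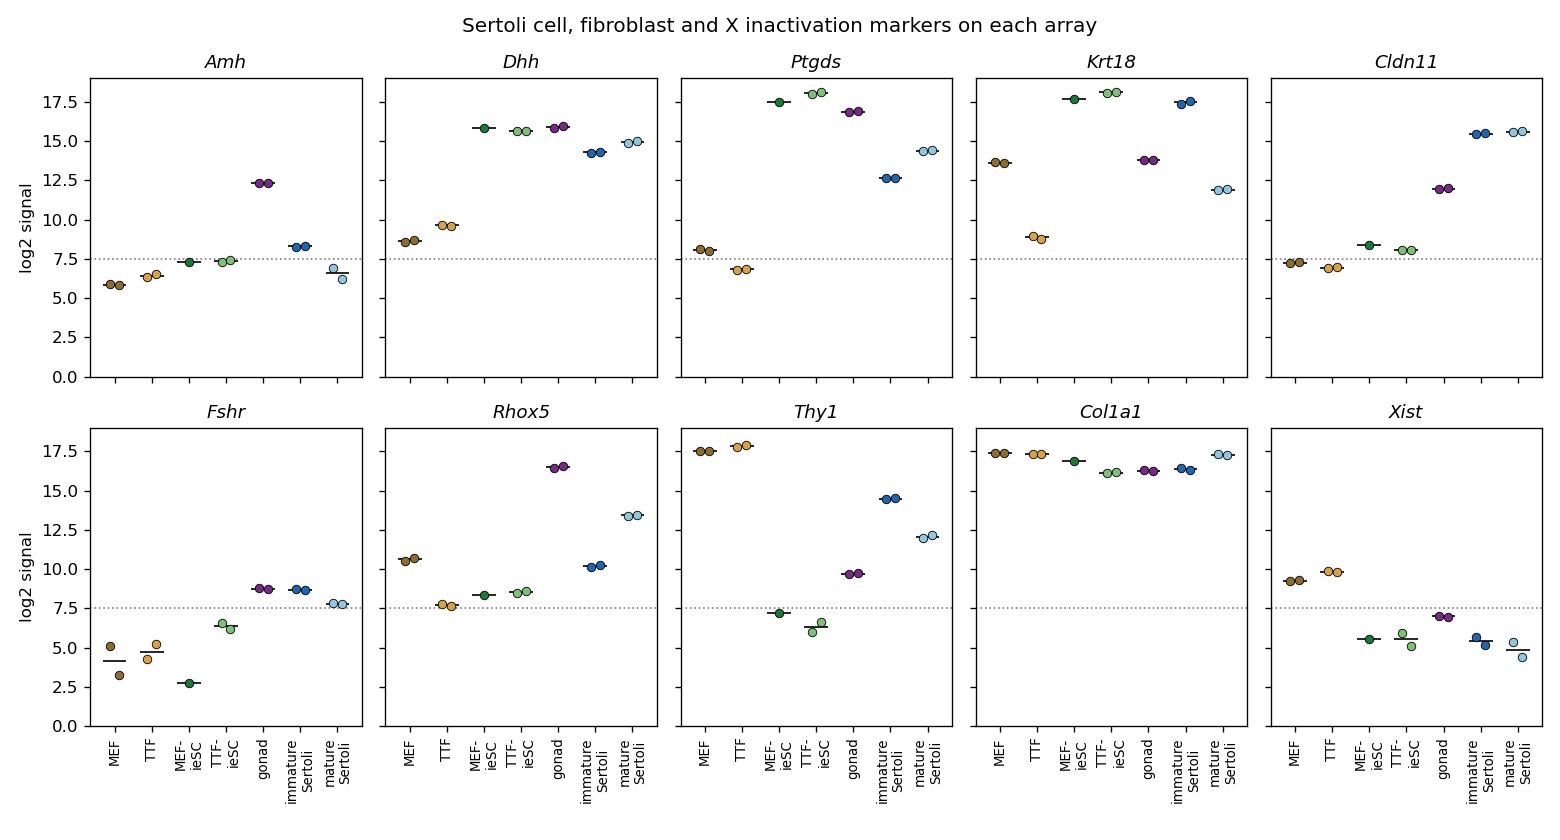
Log2 signal of 10 markers on each array (points) with the group mean (bars) and the array median (dotted line). Dhh, Ptgds and Krt18 are as high in the induced cells as in native Sertoli cells or higher, Amh and Cldn11 lie between 7.30 and 8.39 in them, and Thy1 is at 6.30 and 7.18.

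The difference between the inductions was itself tested, since an effect can pass in 1 of them alone. Wt1 rose by 4.87 ± 0.10 more in TTF-ieSC against TTF than in MEF-ieSC against MEF, and Krt18 by 5.20 ± 0.12 more. The starting cells differed in both genes: Wt1 was 6.81 in TTF and 11.77 in MEF, and Krt18 was 8.87 in TTF and 13.64 in MEF. Cell division genes rose more from TTF, with 36 of 38 higher in the test of the difference and 1 lower (adjusted p = 4.09e-14). Interferon genes fell more from TTF, with 26 of 30 lower and 2 higher (adjusted p = 2.22e-09; 27 lower and 2 higher adjusted over the list alone). Anterior and central Hox genes, which fell from MEF, were split from TTF, with 9 of 20 higher and 11 lower (adjusted p = 0.346; the same counts adjusted over the list alone). In the difference 16 of them were higher and 1 was lower (adjusted p = 4.60e-06; the same counts adjusted over the list alone). With an estimated correlation these 3 lists passed (adjusted p = 0.00288, 0.00498 and 0.0147). The difference equals that of TTF-ieSC and MEF-ieSC, which lay 0.468 apart, minus that of TTF and MEF, which lay 0.998 apart. In TTF against MEF these lists passed in the opposite direction, so these results may reflect the starting cells rather than a different response. Of the genes called and changed by 1 log2 unit or more, 1676 were higher in both inductions, 1785 were lower in both and 93 went opposite ways. Independent lists would share 398, 421 and 819 genes. Across genes, which are not independent replicates, the changes had a Pearson correlation of 0.801 and a Spearman correlation of 0.709. The difference was called for 9010 genes, 4817 higher and 4193 lower.

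TTF-ieSC and MEF-ieSC, compared to see whether the starting cell left a difference, lay 0.468 apart, less than the 0.998 between TTF and MEF and more than the replicate pairs. TTF-ieSC had more Fxyd6 (1.97 ± 0.07) and less Col1a1 (-0.75 ± 0.07). Sox9 was higher by 0.67 ± 0.09. Of the 29 lists only the endothelial list was called, with 6 of 22 genes higher and 0 lower (adjusted p = 0.0472; 7 higher adjusted over the list alone), and it was lost with an estimated correlation (adjusted p = 0.442 with an estimated correlation). A total of 2381 genes was called, 1255 higher and 1126 lower, of which 456 differed by 1 log2 unit or more. A fit on these groups alone called 6 genes.

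TTF and MEF, the starting populations, differed in position genes, cell division and interferon response. Of 38 cell division genes, 36 were lower in TTF and 1 was higher (adjusted p = 3.18e-13), Plk1 by -2.72 ± 0.08 and Mki67 by -2.60 ± 0.04. Of 30 interferon genes, 25 were higher and 1 lower (adjusted p = 6.99e-09), Oas2 by 4.08 ± 0.16 and Zbp1 by 3.43 ± 0.14. Of 20 anterior and central Hox genes, 16 were lower and 0 higher (adjusted p = 4.77e-06), Hoxc6 by -3.28 ± 0.08 and Hoxd8 by -3.27 ± 0.08, while Hoxb13, of the posterior end of its cluster, was higher by 8.16 ± 0.21. The posterior Hox list was split, with 7 of 16 higher and 7 lower (adjusted p = 0.945; 8 higher and 7 lower adjusted over the list alone). The cell division, interferon and anterior and central Hox lists held with an estimated correlation (adjusted p = 0.00347, 0.00581 and 0.0148), with the same counts adjusted over the list alone. Of 16 smooth muscle genes 12 were lower and 2 higher (adjusted p = 0.00332), Itga8 by -4.30 ± 0.09 and Actg2 by -3.46 ± 0.06, which did not hold (adjusted p = 0.0733 with an estimated correlation). The inflammatory list had 16 of 23 genes higher and 6 lower (adjusted p = 0.00332), with Ccl8 at 6.97 ± 0.08 and Mmp3 at 3.25 ± 0.18, and did not hold (adjusted p = 0.0702 with an estimated correlation). Counts for both were the same adjusted over the list alone. The macrophage list had 17 of 23 genes lower and 2 higher (adjusted p = 0.00371; 18 lower adjusted over the list alone), with C1qc at -3.81 ± 0.21 and Ms4a7 at -3.30 ± 0.50, and did not hold (adjusted p = 0.239 with an estimated correlation).

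Single genes set the fibroblasts apart by far more. TTF had more Ifi202b (9.96 ± 0.21), Prl2c5 (9.71 ± 0.09), Cilp (8.07 ± 0.21), the joint lubricant gene Prg4 (7.31 ± 0.59) and Pi16 (7.22 ± 0.07). MEF had more of the cartilage collagen Col2a1 (-8.38 ± 0.14), the hindlimb factor Pitx1 (-7.42 ± 0.12), the fetal growth factor Igf2 (-7.05 ± 0.17), Ptprz1 (-6.77 ± 0.09), Adamts4 (-6.17 ± 0.06) and Fxyd6 (-6.10 ± 0.06). Features of Prg4, Ptprz1 and Adamts4 differed among themselves in TTF-ieSC against TTF (-10.40 to -1.73, 0.31 to 7.12 and -2.51 to 3.37). The values here are those of the brightest feature. Among the factors, Wt1 (-4.96 ± 0.06), Gata4 (-2.24 ± 0.15) and Nr5a1 (-0.91 ± 0.09) were lower in TTF, Sox9 was higher by 0.43 ± 0.07, and Dmrt1 did not pass (adjusted p = 0.235). Rhox5 (-2.91 ± 0.09), Ptgds (adjusted p = 5.05e-07) and Cldn11 (-0.32 ± 0.06) were lower and Dhh (1.02 ± 0.06) was higher. Thy1, Col1a1, Xist and Fshr did not pass (adjusted p = 0.108, 0.372, 0.156 and 0.360). Fshr was dim in both, and went from 1.51 (adjusted p = 0.00590) without MEF replicate 1 to -0.35 (adjusted p = 0.393) without MEF replicate 2. Thy1 passed without either TTF-ieSC array (adjusted p = 0.00781), and Thy1 and Xist passed in a fit on these groups alone (adjusted p = 0.0175 and 0.00249). Amh was higher by 0.57 (adjusted p = 0.0272), which did not pass without MEF replicate 1 (adjusted p = 0.0629), MEF replicate 2 (adjusted p = 0.106), TTF replicate 1 (adjusted p = 0.0574) or TTF replicate 2 (adjusted p = 0.111), nor with array weights (adjusted p = 0.101). In all 11090 genes were called, 5183 higher and 5907 lower.

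The native signature asked how many of the genes that separate immature Sertoli cells from fibroblasts moved the same way in the inductions. MEF and TTF had a Pearson correlation of 0.946 across genes. A gene common to both fibroblasts can therefore enter a set and also change in the induction. The shares and tests below do not separate a gain of Sertoli cell expression from a loss of fibroblast expression. The native samples also had signal of other cells. Dazl was 13.02 and Cyp11a1 13.89 in the immature Sertoli cultures, Ldhc 15.90 in the mature ones and the globin gene Hbb-bt 17.84 in the gonad. The sets of higher genes are therefore not of Sertoli cell genes alone, and their shares do not measure likeness to Sertoli cells alone. Of 2297 genes higher in immature Sertoli cells than in MEF, 52.6% rose and 26.6% fell in TTF-ieSC against TTF, with a median of 0.49. Of all tested genes, 39.5% rose and 35.2% fell in that induction. Of 1740 genes lower in immature Sertoli cells, 67.9% fell and 19.2% rose, with a median of -1.09. Read with TTF as the reference and MEF-ieSC against MEF as the induction, 47.5% of 3144 higher genes rose and 26.6% fell, and 55.0% of 2533 lower genes fell and 24.2% rose, where 34.3% of all tested genes rose and 33.6% fell. In limma's camera the sets moved in the native direction, for TTF-ieSC with adjusted p = 0.000876 for higher and adjusted p = 1.37e-14 for lower genes, and for MEF-ieSC with adjusted p = 0.000876 and adjusted p = 5.94e-07. With an estimated correlation these sets held (adjusted p = 0.0311, 0.00147, 0.0334 and 0.00390), though with genes taken by adjusted p alone the higher set in MEF-ieSC did not (adjusted p = 0.0643). For the gonad signature, 53.0% of 2986 higher and 67.3% of 2304 lower genes followed in TTF-ieSC, and 44.2% of 3842 and 55.4% of 2883 in MEF-ieSC. All 4 gonad sets passed (adjusted p from 7.63e-14 to 0.00339) and held with an estimated correlation (adjusted p from 0.00389 to 0.0311), though with genes taken by adjusted p alone the higher set in MEF-ieSC did not (adjusted p = 0.0594). Of 2634 genes higher in mature Sertoli cells than in MEF, 39.8% rose and 30.1% fell in TTF-ieSC against TTF, where 39.5% and 35.2% of all tested genes did, and the set did not pass (adjusted p = 0.332). The other mature Sertoli sets passed: 60.4% of 1642 lower genes fell in TTF-ieSC (adjusted p = 3.35e-07), and in MEF-ieSC 42.8% of 3035 higher genes rose (adjusted p = 0.00312) and 54.7% of 2189 lower genes fell (adjusted p = 6.26e-06). With an estimated correlation these 3 held (adjusted p from 0.0115 to 0.0184), though with genes taken by adjusted p alone none of the mature Sertoli sets did (adjusted p from 0.0643 to 0.124).

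Over all tested genes the induced cells were no nearer to immature Sertoli cells than their fibroblasts were. TTF-ieSC lay 1.58 from immature Sertoli cells (single array pairs 1.58 to 1.61) and TTF lay 1.53 from them (1.54 to 1.55). MEF-ieSC lay 1.60 (both pairs 1.61) and MEF lay 1.27 (1.28 to 1.30). From their own fibroblasts, TTF-ieSC lay 1.78 and MEF-ieSC 1.64. Immature Sertoli cells lay 1.17 from the gonad. The immature Sertoli cultures were in 10% serum like the fibroblasts, and the induced cells were in 2%. These cultures also had signal of fibroblast and germ cell genes (Thy1 14.49, Dazl 13.02). Against immature Sertoli cells, the distances do not separate serum or other cells in the cultures from Sertoli cell expression. The gonad was not cultured, and the induced cells were no nearer to it either. TTF-ieSC lay 1.769 from the gonad and TTF 1.768, while MEF-ieSC lay 1.786 from it and MEF 1.497. Serum shared with the native sample cannot account for the result against the gonad, which also holds other cells. Distances carry no test.

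**Figure D3:**
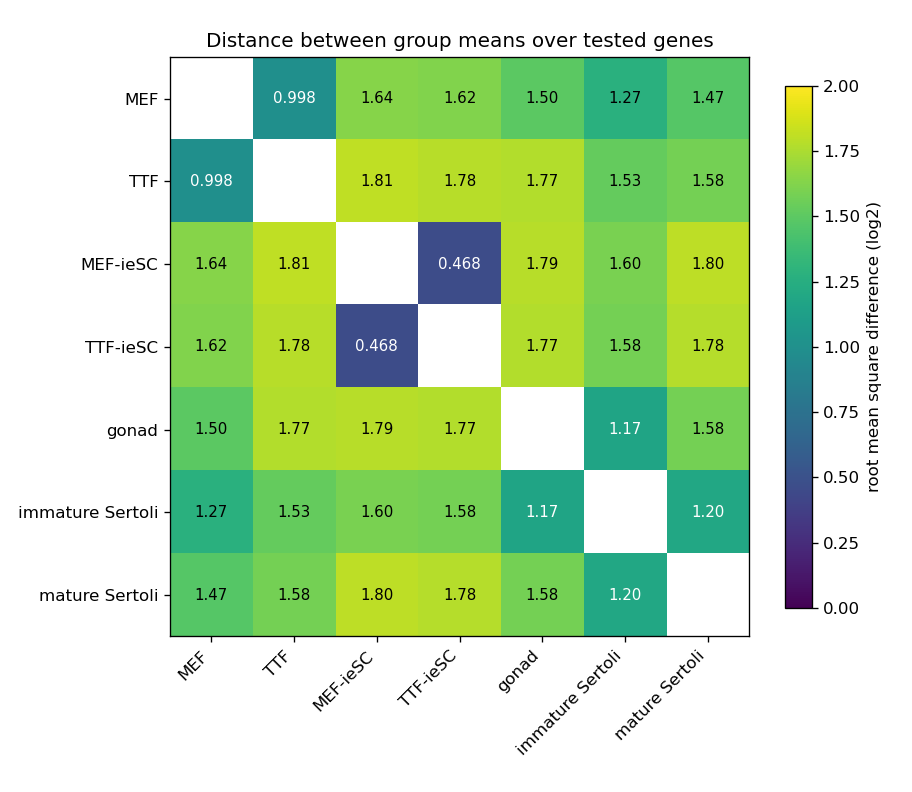
Root mean square log2 difference between the means of each pair of groups over 16658 tested genes, with the value in each square. The closest pair is TTF-ieSC with MEF-ieSC (0.468), and the induced cells lie 1.58 and 1.60 from immature Sertoli cells.

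TTF-ieSC and immature Sertoli cells were compared to see what still separated induced from native cells. Gata4 was lower in TTF-ieSC by -7.24 ± 0.15, Nr5a1 by -4.53 ± 0.09, Sox9 by -3.68 ± 0.07 and Dmrt1 by -2.71 ± 0.08, and Wt1 was higher by 0.84 ± 0.06. The list of 34 embryonic Sertoli cell markers was split, with 12 higher and 17 lower (adjusted p = 0.420). Ptgds (5.43 ± 0.06), Dhh (1.37 ± 0.06) and Krt18 (0.64 ± 0.08) were higher, and Cldn11 (-7.38 ± 0.06), Fshr (-2.29 ± 0.53), Rhox5 (-1.68 ± 0.09) and Amh (-0.94 ± 0.19) were lower. Unlike Krt18, the keratin Krt8 was 12.88 in TTF-ieSC against 16.26 in immature Sertoli cells. Xist was dim in both and did not differ (0.11, adjusted p = 0.775), with a difference of -0.30 without TTF-ieSC replicate 1 and -0.11 without immature Sertoli replicate 2.

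Lists of germ cell, Leydig cell, smooth muscle, fibroblast and interferon genes were lower in TTF-ieSC than in the immature Sertoli cultures. The smooth muscle, fibroblast and interferon lists also fell in TTF-ieSC against TTF, so their gaps need not come from other cells in the cultures. The Leydig cell list had 8 of 15 genes lower and 3 higher in TTF-ieSC against TTF and did not pass there (adjusted p = 0.0864). Of 30 embryonic germ cell genes 26 were lower and 2 higher (adjusted p = 2.07e-06), with the meiosis gene Stra8 at -11.24 ± 0.24 and the germ cell RNA-binding gene Dazl at -8.10 ± 0.31. Of 15 Leydig cell genes 12 were lower and 1 higher (adjusted p = 6.88e-05), with the steroid enzyme gene Cyp11a1 at -8.85 ± 0.42 and Inhba at -7.09 ± 0.06. Inhba was 15.35 in MEF and 15.89 in TTF, near the 16.24 of immature Sertoli cells. Of 16 smooth muscle genes 14 were lower and 2 higher (adjusted p = 2.56e-05), Myl9 by -8.32 ± 0.06 and Actg2 by -7.84 ± 0.06. Of 39 fibroblast genes 26 were lower and 10 higher (adjusted p = 0.000952), Thy1 by -8.19 ± 0.16, Postn by -6.90 ± 0.21 and Col1a1 by -0.24 ± 0.06. Of 30 interferon genes 25 were lower and 4 higher (adjusted p = 2.56e-05), Oas1a by -7.11 ± 0.11 and Ifih1 by -6.47 ± 0.23. Of 20 cholesterol synthesis genes 17 were higher and 2 lower (adjusted p = 0.00193). These 6 lists held with an estimated correlation (adjusted p from 0.0252 to 0.0425), with the same counts adjusted over the list alone. The macrophage list had 19 of 23 genes lower and 0 higher (adjusted p = 4.79e-05; the same adjusted over the list alone), with Ms4a7 at -6.90 ± 0.50 and Ctss at -5.80 ± 0.16, and did not hold (adjusted p = 0.115 with an estimated correlation). The junction list had 20 of 29 genes lower and 5 higher (adjusted p = 0.00393; 21 lower adjusted over the list alone) and did not hold (adjusted p = 0.119 with an estimated correlation). The epithelial list (median -1.86) and the inflammatory list (median -1.87) were also called lower. Neither held in camera with an estimated correlation (adjusted p = 0.115 and 0.0846).

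The genes most above immature Sertoli cells were Slc34a3 (8.79 ± 0.64), the thyroxine carrier Ttr (8.21 ± 0.21), the claudin Cldn15 (7.97 ± 0.06), Tlx2 (7.79 ± 0.15) and the cartilage collagens Col9a1 (7.55 ± 0.38) and Col9a3 (7.55 ± 0.21). The most below, with Stra8, were Cxcl12 (-9.94 ± 0.07), Bves (-9.62 ± 1.05), Prkar2b (-9.37 ± 0.08), Dlk1 (-9.28 ± 0.06) and Crispld2 (-9.07 ± 0.10). The Bves values of the TTF-ieSC arrays differed widely (3.55 ± 3.01, SD). In all 12788 genes were called, 6289 higher and 6499 lower. MEF-ieSC against immature Sertoli cells gave 11763 calls, 5738 higher and 6025 lower, with 26 of 30 embryonic germ cell genes lower and 2 higher (adjusted p = 5.44e-07; adjusted p = 0.0201 with an estimated correlation; the same counts adjusted over the list alone).

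**Figure D4:**
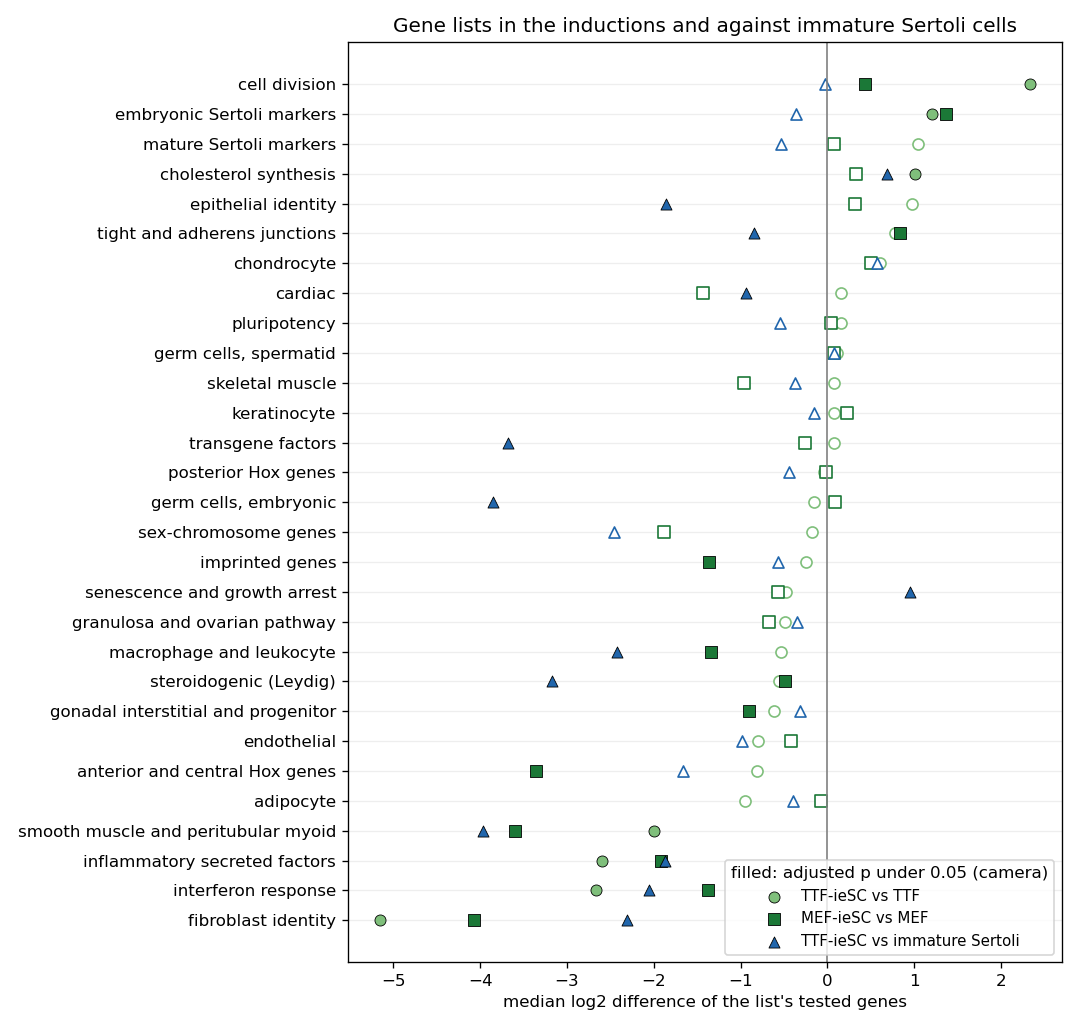
Median log2 difference of the tested genes of each of 29 lists in TTF-ieSC against TTF (circles), MEF-ieSC against MEF (squares) and TTF-ieSC against immature Sertoli cells (triangles), filled where camera passed at the preset correlation. The fibroblast list is lowest in both inductions (-5.15 and -4.07), and the embryonic germ cell list lies at -3.86 against immature Sertoli cells and near 0 in the inductions.

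Against whole gonad, which holds other cells beside Sertoli cells, genes of germ and Leydig cells were lower in TTF-ieSC. In TTF-ieSC 28 of 30 embryonic germ cell genes were lower and 0 higher (adjusted p = 3.67e-08; adjusted p = 0.0133 with an estimated correlation), and so were 15 of 15 Leydig cell genes (adjusted p = 1.44e-06; adjusted p = 0.0263 with an estimated correlation). The globin genes Hbb-bt (-12.67 ± 0.37) and Hbb-b2 (-11.42 ± 0.21) and Cyp11a1 (-10.56 ± 0.42) were lower, and the lower Dppa5a (-10.08 ± 0.11) is a gene of germ and pluripotent cells. The endothelial list, with 17 of 22 genes lower and 2 higher (adjusted p = 0.000247), did not hold (adjusted p = 0.0734 with an estimated correlation), nor did the macrophage list, with 19 of 23 lower and 1 higher (adjusted p = 0.000841; adjusted p = 0.127 with an estimated correlation). Of 34 embryonic Sertoli cell markers 22 were lower and 8 higher (adjusted p = 0.0312), which did not hold (adjusted p = 0.0752 with an estimated correlation). Adjusted over the list alone these 5 lists had the same counts. P2rx2 (7.84 ± 0.09), Tlx2 (7.66 ± 0.15) and Krt18 (4.32 ± 0.08) were higher. TTF-ieSC against gonad gave 13282 calls, 6367 higher and 6915 lower, and MEF-ieSC against gonad 12492, 5983 higher and 6509 lower.

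Against mature Sertoli cells, 22 of 22 spermatid genes were lower in TTF-ieSC (adjusted p = 2.36e-07), Ldhc by -9.94 ± 0.25. Interferon genes were lower, 28 of 30 with 2 higher (adjusted p = 1.19e-07), and cholesterol synthesis genes higher, 19 of 20 with 0 lower (adjusted p = 3.22e-06). With an estimated correlation these lists held (adjusted p = 0.00775, 0.00775 and 0.0109), and adjusted over the list alone their counts were the same. Cxcl12 (-11.10 ± 0.07) and Clec2m (-10.55 ± 0.41) were lower, and P2rx2 (8.44 ± 0.09) and Mest (7.74 ± 0.06) higher. TTF-ieSC against mature Sertoli cells gave 13264 calls, 7164 higher and 6100 lower, and MEF-ieSC 12481, 6728 higher and 5753 lower.

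Mature and immature Sertoli cells were compared in cultures of 7 and 3 days. Stage and days of culture differ together, and the signal of germ cell genes also differed between the cultures. The comparison does not separate stage from culture time or from other cells in the cultures. The changes below therefore need not be those of maturing Sertoli cells. Spermatid genes were higher in the mature cultures, 22 of 22 (adjusted p = 5.06e-11), with the sperm mitochondrial gene Smcp at 6.98 ± 0.50 and the testis lactate dehydrogenase Ldhc at 6.93 ± 0.24. Clec2m (8.90 ± 0.41), Plaat5 (8.27 ± 0.52), Fbp1 (8.05 ± 0.21), Slc6a21 (7.80 ± 0.55), and Hils1 (7.71 ± 0.25) and Pabpc2 (7.40 ± 0.30), both of sperm-forming cells, had the largest rises among the named genes. Epithelial genes were lower, 24 of 27 with 0 higher (adjusted p = 6.54e-08), Krt8 by -7.24 ± 0.10, Krt19 by -5.79 ± 0.07 and Krt18 by -5.55 ± 0.08. Cholesterol synthesis genes were lower, 18 of 20 with 2 higher (adjusted p = 0.000254), Dhcr7 by -1.64 ± 0.07, while Sc5d was higher by 1.48 ± 0.08. Fibroblast genes were higher, 26 of 39 with 9 lower (adjusted p = 0.000648), Dpep1 by 3.58 ± 0.09, S100a4 by 2.80 ± 0.06 and Col1a1 by 0.91 ± 0.06, though Thy1 was lower by -2.42 ± 0.16. Embryonic germ cell genes were lower, 20 of 30 with 1 higher (adjusted p = 0.000917), Kit by -4.09 ± 0.12 and Stra8 by -3.95 ± 0.24. These 5 lists held with an estimated correlation (adjusted p from 0.00697 to 0.0322), with the same counts adjusted over the list alone.

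The junction list had 23 of 29 genes lower and 5 higher (adjusted p = 0.000693), with Cldn6 at -4.63 ± 0.24 and Cldn3 at -4.28 ± 0.06, and did not hold (adjusted p = 0.0748 with an estimated correlation). The list of mature Sertoli cell markers had 13 of 26 genes higher and 5 lower (adjusted p = 0.0411), and did not hold (adjusted p = 0.0927 with an estimated correlation), nor without immature Sertoli replicate 1 (adjusted p = 0.0697), immature Sertoli replicate 2 (adjusted p = 0.0664) or mature Sertoli replicate 1 (adjusted p = 0.0503). Both had the same counts adjusted over the list alone. Rhox5, a homeobox gene of the maturing testis, was higher by 3.21 ± 0.09, Ptgds by 1.75 ± 0.06 and Dhh by 0.67 ± 0.06, and Amh was lower by -1.71 ± 0.19. Trim12a (-6.51 ± 0.32), Crisp3 (-6.17 ± 0.32), Krt17 (-6.11 ± 0.33), Wfdc2 (-6.10 ± 0.17) and Bcan (-5.99 ± 0.14) were lower. Among the factors Nr5a1 was higher by 0.40 ± 0.09, and Dmrt1 (-1.59 ± 0.08), Sox9 (-0.68 ± 0.07) and Gata4 (-0.65 ± 0.15) were lower. Wt1 was lower by -0.22 (adjusted p = 0.0163), which did not pass without mature Sertoli replicate 1 or without immature Sertoli replicate 2 (adjusted p = 0.0763), nor in a fit on these groups alone (adjusted p = 0.0624). Cldn11 was higher by 0.14 (adjusted p = 0.0496), a call lost with no filter (adjusted p = 0.0642), with a variance trend (adjusted p = 0.0508), with array weights (adjusted p = 0.0542) and on these groups alone (adjusted p = 0.136). It was also lost without immature Sertoli replicate 1 or any single MEF, TTF-ieSC, gonad or mature Sertoli array (adjusted p from 0.0509 to 0.191). Fshr (-0.87, adjusted p = 0.174) and Xist (-0.55, adjusted p = 0.178) did not pass, though Fshr did without either MEF array (adjusted p = 0.0239) and on these groups alone (adjusted p = 0.000442) and Xist without mature Sertoli replicate 1 (-1.02, adjusted p = 0.0242). In all 11407 genes were called, 4813 higher and 6594 lower.

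Immature Sertoli cells after 3 days of culture were compared with the uncultured gonad. Interferon genes were higher in the cultures, 27 of 30 with 2 lower (adjusted p = 3.55e-08), Usp18 by 4.86 ± 0.10 and Oas1a by 4.04 ± 0.11. Inflammatory factors were higher, 21 of 23 with 2 lower (adjusted p = 7.08e-08), Lcn2 by 7.86 ± 0.08 and the prostaglandin synthase Ptgs2 by 6.48 ± 0.09. Epithelial genes were higher, 22 of 27 with 2 lower (adjusted p = 1.07e-05), Krt7 by 4.30 ± 0.07 and Mal2 by 3.98 ± 0.29. Imprinted genes were lower, 23 of 29 with 2 higher (adjusted p = 1.07e-05), Mest by -5.24 ± 0.06 and Asb4 by -5.16 ± 0.04. Pluripotency genes were lower, 12 of 12 (adjusted p = 1.40e-05), Dppa5a by -5.48 ± 0.11 and Utf1 by -5.21 ± 0.06. These 5 lists held with an estimated correlation (adjusted p from 0.0104 to 0.0251). Endothelial genes were lower, 18 of 22 with 2 higher (adjusted p = 1.71e-05), Cldn5 by -4.40 ± 0.07 and Mmrn2 by -4.02 ± 0.07, which did not hold (adjusted p = 0.0556 with an estimated correlation). Adjusted over the list alone these 6 lists had the same counts.

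The globin genes Hbb-y (-11.20 ± 0.21), Hbb-b2 (-9.35 ± 0.21), Hbb-bt (-9.05 ± 0.37) and Hba-x (-8.58 ± 0.53) were lower in the cultures, as were Cst9 (-9.50 ± 0.62) and the germ cell gene Dppa3 (-9.44 ± 0.77). The Hbb-y feature lies in an uneven block of the array grid. Cxcl14 (7.83 ± 0.11), Ankrd1 (7.82 ± 0.08), Cidea (7.00 ± 0.11), Reg3b (6.96 ± 0.38) and Ltbp2 (6.67 ± 0.07) were higher. Of the Sertoli cell markers, Rhox5 (-6.31 ± 0.09), Ptgds (-4.24 ± 0.06), Amh (-4.04 ± 0.19) and Dhh (-1.61 ± 0.06) were lower, and Krt18 (3.68 ± 0.08) and Cldn11 (3.49 ± 0.06) higher. Among the factors Nr5a1 was lower by -1.84 ± 0.09, and Sox9 (1.17 ± 0.07) and Dmrt1 (0.98 ± 0.08) were higher. Thy1 was higher by 4.78 ± 0.16 and Xist lower by -1.56 ± 0.33. Gata4, Fshr and Col1a1 did not pass (adjusted p = 0.271, 0.902 and 0.0866), though Col1a1 did without immature Sertoli replicate 2 (0.17, adjusted p = 0.0310). Wt1 was lower by -0.23 (adjusted p = 0.0117), which did not pass without immature Sertoli replicate 1 (adjusted p = 0.0578) or gonad replicate 2 (adjusted p = 0.0549). In all 11750 genes were called, 5435 higher and 6315 lower.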

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

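The test for male cells in the induced samples, and the way the intervals of the sensitivity test and of the corner test were read, were settled only after the result was seen.

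In the induced cells, Xist and the Y-linked gene Eif2s3y were both low: Xist was 5.53 in TTF-ieSC and in MEF-ieSC against 9.84 in TTF and 9.26 in MEF, and Eif2s3y was 5.12 and 6.00 in the induced cells against 11.09 in MEF and 5.97 in TTF. Male cells with an expressed Y chromosome would have Eif2s3y near the native male samples, but its highest induced array lay 6.72 below the lowest of those over 9 arrays, a value that is itself part of the pattern. For 2 active X chromosomes in the TTF-derived cells, a rise of X-linked genes had been named. The 679 X-linked genes changed by -0.11 (95% interval -0.20 to -0.02) relative to autosomal genes in TTF-ieSC against TTF. The same measure was 0.28 for immature Sertoli cells, from testis, against TTF and -0.33 for TTF-ieSC against immature Sertoli cells. It thus also shifts between cell types, so the value does not decide about the X chromosomes. Lower sensitivity for moderate signal stays open: the 1543 genes with a fibroblast mean from 9 to 10 had a median change of 0.12 (0.07 to 0.17), but the distribution shared by all arrays largely fixes that median. Cells with a single X and no Y, as loss of a sex chromosome in 6 months of culture may leave, also stay open and were not tested, and the labels do not give the sex of the fibroblasts' donors.

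TTF-ieSC and MEF-ieSC were closer to each other than TTF and MEF. The same RNA on different arrays is argued against by 51 genes, of 5598 with several features, that were 1 log2 unit or more apart in every feature (54 against the other TTF-ieSC array), where replicate arrays gave at most 9. That count would also arise from separate cultures of the same cells, which stays open, as does a shared effect of the factors and of 6 months in the same medium. For a lasting trace of the fibroblast of origin, a slope of 0.1 or more had been named over the 11090 genes called between TTF and MEF. The slope was 0.0192 (95% interval 0.00964 to 0.0295), under that size. The interval is positive, so a weaker trace, or a trace in fewer genes, stays open. It resamples genes, which are not independent, and rests on 1 MEF-ieSC array.

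Adgra2 and Aldh9a1 stood at 2.38 and 1.99 on the MEF-ieSC array and above 11 in every other group. The 121 features within 5 grid positions of these 2 had a median of -1.21 against the TTF-ieSC arrays (95% interval -2.05 to -0.84), where all features had 0.01. A median under -1 had been named for damage to that region, so the values are consistent with it as a candidate cause, though the interval reaches beyond -1. All 19 features that were 6 or more lower on this array lay at this edge, in lines 18 to 34 of the grid, and in the same region immature Sertoli replicate 2 was lower than replicate 1 by a median of -1.06. Each gene has 1 feature, so no other value can decide for it, and a biological explanation was not tested.

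The changes in the inductions differed in a test of the difference for 14 of the 22 genes named for both and for 31 of the 44 named for either. The values here are the change in TTF-ieSC against TTF minus the change in MEF-ieSC against MEF. They include the difference between TTF and MEF with its sign reversed, and so do not alone show a different response. Of the factors, Wt1 differed by 4.87, Gata4 by 2.24 and Nr5a1 by 1.35. Of the Sertoli cell markers, Krt18 differed by 5.20, Rhox5 by 3.07, Fshr by 3.06, Ptgds by 1.78 and Dhh by -1.22. Of the fibroblast and muscle genes, Actg2 differed by 3.19, Myl9 by 1.15, Thy1 by -1.21 and Col1a1 by -0.69. Ifih1 differed by -2.86 and Cxcl12 by -0.64. Thy1, Fshr, Cxcl12, Ifih1 and Gata4 were under the array median in both kinds of induced cell, and Wt1 and Ptgds were under it in TTF, so these differences depend on the background.

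The median difference between the inductions, which also includes that of TTF and MEF, passed the test in 12 lists as well. It was 2.03 for cell division, 1.94 for anterior and central Hox genes, -1.50 for interferon response and -1.02 for inflammatory factors, which held with an estimated correlation. The other 8 did not hold with it: cardiac genes (1.47), skeletal muscle (1.44), the factors (1.35), macrophages (1.11), smooth muscle (0.87), cholesterol synthesis (0.66), fibroblast identity (-0.21) and adipocytes (-1.04). Adjusted p with an estimated correlation was 0.0610 for cardiac genes and adipocytes, the lowest of these 8, and 0.245 for skeletal muscle and macrophages, the highest.

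Of 31511 features with no gene name, which no comparison used, 13487 were tested in the same way. A rise of 1 log2 unit or more was called for 1312 of them in TTF-ieSC against TTF and for 1132 in MEF-ieSC against MEF, and a fall of that size for 1288 and 1138. Control features are not marked in the table, so these features include any that passed the filter.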

How the results depend on the processing

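Leaving out the features in uneven blocks of the grid was the alternative chosen only after the result was seen. Quantile normalization and the common 75th percentile moved nothing, since the deposited arrays already share 1 distribution, and so say nothing about stability. With them, no filter, the stricter filter, the mean of features, the variance trend, array weights, the replicate block, uneven blocks and every array left out, all 15 counts of called genes stayed within 1.5 times. Counts with an array left out ranged from 11541 to 12670 for TTF-ieSC against TTF, from 10801 to 11560 for MEF-ieSC against MEF, and from 1668 to 2646 for TTF-ieSC against MEF-ieSC. Of the counts, the fit on the compared groups alone moved TTF-ieSC against MEF-ieSC, to 6, with fewer arrays to estimate the spread. That fit also changed 5 named results: Thy1 and Xist in TTF against MEF and Fshr in mature against immature Sertoli cells passed, and Wt1 and Cldn11 in the latter no longer did.

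A minimum log2 difference of 1 lowered every count by its construction: to 5615 for TTF-ieSC against TTF, 4860 for MEF-ieSC against MEF, 3344 for the difference between the inductions, 456 for TTF-ieSC against MEF-ieSC, 3208 for TTF against MEF, 5230 and 5177 for TTF-ieSC and MEF-ieSC against immature Sertoli cells, 5949 and 5922 against gonad, 5842 and 5776 against mature Sertoli cells, 4037 and 5677 for immature Sertoli cells against MEF and TTF, 3551 for mature against immature Sertoli cells and 4041 for immature Sertoli cells against gonad.

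The share of signature genes that followed in TTF-ieSC, for higher and lower genes, was 48.5% and 63.7% with no filter, and 57.9% for higher genes with the stricter filter. For lower genes it was 52.2% with adjusted p alone and 75% at a difference of 2. In MEF-ieSC it was 44.4% and 51.0% with no filter, 52.3% and 59.0% with the stricter filter, 43.3% and 43.9% with adjusted p alone, and 65.5% for lower genes at 2. With an array left out the share of higher genes in TTF-ieSC ranged from 49.7% to 54.1%. For settings that change the genes counted, that is the cause; for the array left out, the cause was not tested.

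Distances from immature Sertoli cells to MEF, TTF, TTF-ieSC and MEF-ieSC, then TTF-ieSC to MEF-ieSC and MEF to TTF, changed with the genes counted. They were 1.33, 1.64, 1.69, 1.69, 0.421 and 1.06 with the stricter filter, 1.24, 1.49, 1.53, 1.55, 0.453 and 0.969 with the mean of features, 1.19, 1.42, 1.46, 1.49, 0.571 and 0.958 over all named genes, and 2.24, 2.63, 2.85, 2.88, 0.802 and 1.65 in the most variable 25% of tested genes. Without uneven blocks MEF-ieSC lay 1.59 from immature Sertoli cells and 0.416 from TTF-ieSC. With an array left out they ranged from 1.27 to 1.29, 1.53 to 1.54, 1.58 to 1.59, 1.60 to 1.61, 0.468 to 0.495 and 0.998 to 1.02.

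Of 85 lists called in 7 comparisons, 41 held with an estimated correlation and 44 did not. Without uneven blocks 2 were lost, the endothelial list in TTF against MEF (adjusted p = 0.0695) and the epithelial list in TTF-ieSC against immature Sertoli cells (adjusted p = 0.0619). Of the list results with an array left out, 36 were lost and 1045 held. Of 218 results for named genes, 3 changed sign with an array left out, and the cause was not tested: Xist in TTF-ieSC against immature Sertoli cells, to -0.30 and -0.11 (with 0.52 the highest value), and Fshr in TTF against MEF, to -0.35. Others with an array left out passed in 14 cases where they had not, and no longer passed in 19.

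The replicate block set title numbers 1 to 8 against 9 to 16. It gave 12866 calls for TTF-ieSC against TTF, changed the call of 3 named results (Nr5a1 and Dmrt1 in MEF-ieSC against MEF, Col1a1 in immature Sertoli cells against gonad, which passed with adjusted p = 0.0457, 0.0165 and 0.0450) and left the other 215. The labels do not say that a number marks a batch, and 4 of 15 pairs of groups deviated together with a correlation above 0.1 (range 0.013 to 0.184). These included gonad with immature Sertoli cells (0.123), gonad with mature Sertoli cells (0.176) and immature with mature Sertoli cells (0.184). What signal over background limits cannot be stated, since background is not given, and falls to values under the array median depend on it.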

Other observations

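The genes printed here beyond those of the rule for named genes were chosen only after the result was seen.

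Some cartilage genes rose in TTF-ieSC against TTF and others fell. Of 21 chondrocyte genes 13 were higher and 6 lower there, and 12 and 6 in MEF-ieSC against MEF, and the list passed in neither (adjusted p = 0.128 and 0.172). From TTF, the cartilage collagens Col9a3 (7.94), Col11a2 (6.56) and Col2a1 (3.87), the matrix gene Acan (4.40) and the factor Sox6 (4.28) rose, and Comp (-6.17) and Col10a1 (-3.88) fell. Col9a1 rose by 6.79 in its brighter feature and differed by 0.40 in the other. From MEF, Col9a3 (7.16), Col11a2 (6.77), Sox6 (3.74) and Acan rose and Col2a1 fell by 4.17, from 15.11 to 10.93. Col9a3 is also in the list of embryonic Sertoli cell markers, and the gonad had 10.48 of it against 13.61 in TTF-ieSC and 6.06 in immature Sertoli cells.

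Imprinted genes moved in both directions in TTF-ieSC against TTF, with 12 of 29 higher and 13 lower (adjusted p = 0.371). Mest rose by 8.54 to 17.95, and H19 (2.97) and Peg3 (2.99) rose. Meg3 (-10.53), Dlk1 (-8.68) and Dio3 (-6.33), which lie in 1 imprinted domain, fell together with Slc22a18 (-6.79) and Ndn (-5.65). Mest was 18.03 in MEF-ieSC, 16.72 in the gonad and 11.48 in immature Sertoli cells.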
